A study of Sus scrofa with 7 samples.

How the data were processed

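RNA was taken from pig myocardium 14 weeks after infarction, and per the labels' protocols total RNA was extracted with a Qiagen kit and libraries were made with a TruSeq kit that depletes ribosomal RNA. The 7 libraries carry the labels hrLuc (3) and S100a1 (4), taken from their titles. The labels give no batch, date or litter. Each library also has a number, which is 33, 39 and 45 in hrLuc replicates 1 to 3. In S100a1 replicates 1 to 4 it is 57, 9, 15 and 21. Whether the numbers follow the order of processing is not known here. They do not alternate between the labels, so a batch that followed them could not be told apart from the label. The data are 1 table of 63562 transcript rows with RefSeq accessions, gene symbols, 7 columns of per-library values and the authors' comparison. The submitters' processing notes name the genome build Sscrofa11.1, R 4.1.2, FastQC 0.11.8 and DESeq2 1.33.1 with no role or order. The aligner, the counting program and its handling of strand, shared reads and the human S100A1 sequence are not given in the sources used here.

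The deposited per-library values are a signal, namely read counts per transcript divided by 1 size factor per library. In each library 100% of the values were whole multiples of the value of 1 read, within 0.01 read, and 1 read was worth 0.824 to 1.14 normalized units, so whole reads could be recovered. The deposited log2 column and the deposited ratio column give the authors' fold change of S100a1 over hrLuc, and the deposited p-value column holds their adjusted p, whose adjustment is not named in the file headers. These were copied as the authors' own. All 63562 rows matched a gene of the RefSeq table, which gave positions on Sscrofa11.1. Of the rows, 33948 had values identical to another row of the same gene, so the same reads can stand in several rows, although the counting mode is not known. The row with the highest mean over the 7 libraries was kept for each of 20653 genes, a choice made after the data had been seen. Reads can also be shared between overlapping genes, which are named as such, and between close paralogs.

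The tests had been fixed for whole counts, with a branch for normalized values, and because the file holds normalized values that branch was used. Genes with at least 10 normalized counts in at least 3 libraries were kept, and limma 3.58.1 (R 4.3.3) was fitted with a mean-variance trend to log2(value + 0.5), without covariates. Its test had 5 residual and 3.84 prior degrees of freedom, was two-sided and was adjusted by Benjamini-Hochberg over 15661 genes with a threshold of 0.05. A fold change on this scale understates the change of genes with few reads. Gene lists with at least 5 measured members, 29 of function and 16 of cell types out of 46 fixed before the data were examined, were tested with camera at its preset correlation of 0.01 and adjusted over 45 lists. The list of mitochondrially encoded transcripts had 0 measured members. Camera with an estimated correlation, fry, and exact permutation of the list scores over the 35 splits of 7 libraries were run beside it. The smallest exact p in this design is 0.0286. No test of depth intervals was needed, because each group has replicates.

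Named genes followed a rule fixed before the data were examined. They are S100A1, in each direction the genes past the threshold with separated groups and a mean of at least 20 normalized counts (or, when fewer than 5 pass, the 5 with the smallest p, given as values), up to 4 members of each called list, and 9 reference genes of remodelling and calcium handling. Here 1 gene passed in each direction, so the 5 of smallest p among genes with a symbol stand in each. Placeholder names beginning with LOC were read as no symbol when the rule was applied to the data, which left out 2 lower loci. Genes named from the authors' table are the list members past its threshold.

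The alternatives fixed before the data were examined were quantile normalization, median centring, no filter, a filter of 50, a robust prior, other pseudocounts, the replicate number as a block, removal of 3 genes above 1% of the reads, each library left out, a threshold of 0.10, and other list tests. DESeq2 and limma-voom had been fixed for whole counts only. Those added after seeing the data were edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the recovered reads, the lowest or middle transcript row, genes without overlap, and removal of each library's trend with gene span. The fits were tested on simulated counts for the 15661 genes of this comparison, drawn 5 times with 200 genes changed. Each gene was drawn independently of the others. Variation shared between genes was not simulated, so the shares of false calls may differ in these libraries. limma recovered 37.0% of genes changed 1.5-fold, 72.8% of those changed 2-fold and 94.5% of those changed 4-fold, and 5.29% of its calls were false. DESeq2 recovered 56.4%, 81.8% and 95.5%, and 17.7% of its calls were false, above the 5% that its threshold allows. edgeR recovered 39.7%, 72.5% and 94.8%, with 5.36% false. Tables were handled and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.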

Results

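Gene expression was measured by RNA sequencing in heart muscle from the anteromidventricular region of male farm pigs, 14 weeks after a myocardial infarction in the territory of the left circumflex coronary artery. The animals had received an adeno-associated virus of serotype 5 (AAV5), a vector that carries a gene into tissue. In 4 libraries, labelled S100a1, the vector carried human S100A1, a calcium-binding protein of heart muscle, and in 3 libraries, labelled hrLuc, it carried luciferase, a reporter enzyme. The sample titles describe each library as a separate pig. With 1 transcript row kept per gene, the libraries held 28679324 to 38409552 reads, with a mean of 30573271 ± 2187197 (SD, n = 3) in hrLuc and 33941674 ± 4712583 (SD, n = 4) in S100a1. TTN, which encodes the giant sarcomere protein titin, took 7.97% to 11.4% of the reads of a library. Of 20653 genes, 15661 had enough reads to be tested. Fold changes are S100a1 over hrLuc throughout, on the log2(value + 0.5) scale, and the error of a fold change is its standard error.

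The design asked what S100A1 delivery changed in the infarcted heart relative to the luciferase vector, and the delivered gene was examined first. The pig S100A1 gene (Sscrofa11.1, chromosome 4, 96007026 to 96012305) was not higher in the libraries labelled S100a1. Its normalized read count was 7718 ± 1298 (SD, n = 3) in hrLuc and 5933 ± 1064 (SD, n = 4) in S100a1. The log2 fold change was -0.39 ± 0.16, with an adjusted p of 0.577 in limma, and the exact two-sided permutation test of the 7 values gave p = 0.114. With a library left out the log2 fold change ran from -0.50 to -0.25. The vector carried the human sequence, and whether its reads were counted on the pig transcripts is not given in the sources used here, so this gene does not check the labels. The libraries are therefore named by their labels, and each direction below rests on those labels. S100A1 overlaps S100A13, so the counts of the 2 genes can hold the same reads.

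**Figure D1:**
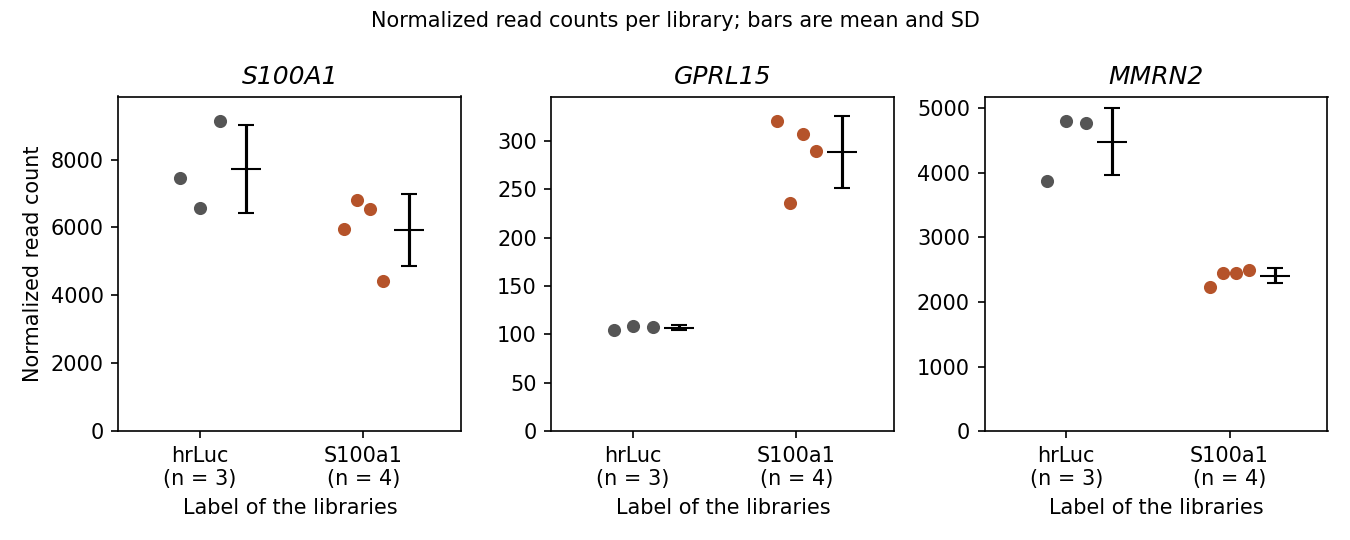
Normalized read count of S100A1, GPRL15 and MMRN2 in each library, by label, where points are the 3 hrLuc and 4 S100a1 libraries and bars are the mean and SD. The S100A1 values of the 2 labels overlap, the 4 S100a1 libraries lie above the 3 hrLuc libraries for GPRL15, and they lie below them for MMRN2.

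GPRL15 rose and MMRN2 fell in the libraries labelled S100a1, and these were the 2 genes past the threshold of 0.05. GPRL15, described in the table as the homologue of a human open reading frame, lies on chromosome 14 from 85404074 to 85421474. Its count was 107 ± 2.40 (SD, n = 3) in hrLuc and 288 ± 37.1 (SD, n = 4) in S100a1, a log2 fold change of 1.41 ± 0.13 (adjusted p = 0.0300, limma). MMRN2, an endothelial matrix glycoprotein, lies on chromosome 14 from 87891585 to 87916327 and overlaps BMPR1A. Its count was 4479 ± 522 (SD, n = 3) in hrLuc and 2404 ± 115 (SD, n = 4) in S100a1, a log2 fold change of -0.89 ± 0.09 (adjusted p = 0.0300, limma). In both genes the values of the 2 groups did not overlap. The next genes did not pass. On the higher side they were GPC5, a cell-surface heparan sulphate proteoglycan (log2 fold change 1.52, adjusted p = 0.0547 in limma, with S100a1 replicate 1 far above the other 3), CDHR1, a neighbour of GPRL15 (1.12), PLA2G4A, a cytosolic phospholipase (0.44), and ASB15 (0.41). On the lower side they were KCNA5, a potassium channel (-0.83), TSPAN2, a tetraspanin (-0.68), GPC1, another glypican (-0.54), and TP53I11 (-0.46). The rule for named genes passed over 2 lower loci without a gene symbol that have a smaller p than GPC1, given here after their values were seen. LOC100520329, a membrane primary amine oxidase, was at -0.55 (adjusted p = 0.134, limma), and the uncharacterized LOC106506856 had a mean of 61.3 normalized counts in hrLuc and 1.11 in S100a1 (adjusted p = 0.247, limma). The adjusted p reached 0.342 for PLA2G4A (limma). PLA2G4A overlaps PTGS2 and TP53I11 overlaps TSPAN18.

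Both calls lay close to the threshold, and most fits with 1 library fewer did not call them although the fold changes moved little. The log2 fold change of GPRL15 stayed between 1.36 and 1.51 with each library left out, but its call was lost without hrLuc replicate 1 (adjusted p = 0.0891, limma), hrLuc replicate 2 (0.108), hrLuc replicate 3 (0.177), S100a1 replicate 1 (0.101), S100a1 replicate 3 (0.123) or S100a1 replicate 4 (0.0996). That of MMRN2 stayed between -0.99 and -0.84, and its call was lost without hrLuc replicate 2 (adjusted p = 0.108, limma), hrLuc replicate 3 (0.179), S100a1 replicate 1 (0.101), S100a1 replicate 2 (0.121), S100a1 replicate 3 (0.123) or S100a1 replicate 4 (0.0996). With median centring MMRN2 did not pass (0.0606, limma). At an unadjusted p under 0.05 there were 1294 genes, or 769 without hrLuc replicate 1. The groups did not overlap in 9.27% of the genes tested, where chance gives 5.71% on average. Genes are not independent replicates, so these 2 shares do not test for an excess. Of the 35 splits of the 7 libraries into 3 and 4, the labelled one included, 4 gave at least 1294 genes at an unadjusted p under 0.05. On the whole reads recovered from the table, edgeR called 2 genes, limma-voom called 0 (1279 at an unadjusted p under 0.05) and DESeq2 called 100.

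Lists of fibrillar collagens and matrix and of fibroblast markers were lower in the libraries labelled S100a1. Of 40 measured genes of the list of fibrillar collagens and matrix, 38 had a negative log2 fold change, with a median of -0.26 (adjusted p = 1.98e-07, camera with its preset correlation, and adjusted p = 0.763 with an estimated correlation). The estimated correlation of this list was 0.26, against the preset of 0.01. The members with the smallest p were MFAP4, a microfibril protein (-0.50 ± 0.12, overlapping MAPK7), ELN, elastin (-0.60 ± 0.15), LOXL1, which crosslinks elastin (-0.49 ± 0.13), and COL8A1, a short-chain collagen (-0.51 ± 0.14). The markers of activated fibroblasts were lower (12 of 14 negative, median -0.28, adjusted p = 0.0118, camera, and adjusted p = 0.763 with an estimated correlation), with COL8A1, CILP (-0.77), THBS4 (-0.28) and RUNX1 (-0.27) the members of smallest p. The general fibroblast markers were lower too (13 of 15 negative, median -0.14, adjusted p = 0.0350, camera, and adjusted p = 0.825 with an estimated correlation), with SERPINF1, which encodes a secreted antiangiogenic factor, at -0.69, PI16 at -0.49, LUM at -0.31 and COL1A1 at -0.44. These 3 lists share members, so their calls are not separate results. COL8A1, CILP and THBS4 also stand in the matrix list, as do LUM and COL1A1 of the fibroblast list. Among these 3 lists, SERPINF1 was the 1 member past the threshold adjusted over the list alone (0.0108, limma), and it overlaps SMYD4. Matrix proteases and their inhibitors (median -0.14, adjusted p = 0.191, camera) and TGF-beta and myofibroblast signalling (median -0.12) did not pass. The matrix list passed with each library left out, but its median was -0.17 without hrLuc replicate 1. The activated fibroblast call was lost without hrLuc replicate 1 (median -0.17, adjusted p = 0.0690, camera) or hrLuc replicate 2 (-0.31, 0.0554). The fibroblast call was lost without hrLuc replicate 1 (median -0.066, adjusted p = 0.338, camera) or S100a1 replicate 1 (-0.060, 0.266) and among genes without overlap (0.0572), and its median was -0.25 without hrLuc replicate 2 and -0.22 without S100a1 replicate 3. The library scores of the groups overlapped for the general fibroblast list. Single members moved by over 1.5 times: LUM was at -0.16 without hrLuc replicate 1, CILP at -0.46 without hrLuc replicate 3, PI16 at -0.32 without S100a1 replicate 1 and THBS4 at -0.18 without S100a1 replicate 4.

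Of the immune lists, those for T and natural killer cells, antigen presentation, the type I interferon response and innate sensing were lower in the libraries labelled S100a1, and 5 others did not pass. Markers of T and natural killer cells had a median of -0.62, with 21 of 23 negative (adjusted p = 1.79e-05, camera, and adjusted p = 0.763 with an estimated correlation). CD5, a T cell surface receptor, was at -1.11 ± 0.23 and was the 1 member past the threshold adjusted over the list alone (0.0211, limma). CD4 was at -0.80, GZMH, a granzyme, at -1.16 and CD3E, a chain of the T cell receptor complex, at -0.79. Antigen presentation genes were lower (26 of 28 negative, median -0.25, adjusted p = 2.50e-05, camera, and adjusted p = 0.763 with an estimated correlation). Among them were TAP1, a transporter (-0.45), and TAPBP, which encodes the TAP binding protein (-0.36, overlapping ZBTB22). The class I genes SLA-8 (-0.52) and SLA-6 (-0.37), close paralogs whose reads can be shared, were among them too. All 35 measured genes of the type I interferon response had a negative log2 fold change, with a median of -0.31 (adjusted p = 4.25e-04, camera, and adjusted p = 0.825 with an estimated correlation). BST2 (-0.54), USP18 (-0.54), RTP4 (-0.51) and STAT2 (-0.31, overlapping IL23A) had the smallest p. Genes of innate sensing and NF-kB signalling were lower by a median of -0.09, with 24 of 34 negative (adjusted p = 0.0420, camera, and adjusted p = 0.763 with an estimated correlation), and the smallest p were those of RELB (-0.43), TLR5 (-0.37), TICAM1 (-0.33) and TLR8 (-0.45, overlapping TLR7). Cytokines and chemokines (17 of 36 positive, median -0.03, adjusted p = 0.891, camera), complement and coagulation (median -0.03, 0.771), macrophages and monocytes (median -0.03, 0.554), neutrophils and mast cells (median 0.02, 0.269) and B and plasma cells (median -0.20) did not pass. The interferon score of hrLuc replicate 1 was 0.81, against -0.43 to 0.18 in the other 6 libraries, and without that library the median was -0.03 and the call was lost (adjusted p = 0.669, camera). Without hrLuc replicate 2 the interferon median was -0.56. The innate sensing call was lost without hrLuc replicate 1 (median -0.079, adjusted p = 0.404, camera), S100a1 replicate 1 (-0.059, 0.123) or S100a1 replicate 2 (-0.11, 0.0695), and its median was -0.15 without hrLuc replicate 2. It was also lost with quantile normalization (median -0.064, adjusted p = 0.132, camera), a stricter filter (-0.089, 0.0514), genes without overlap (-0.091, 0.0651), the gene span trend removed (-0.059, 0.0701) and cameraPR (0.0538). Over all settings the median of this list ran from -0.15 to -0.044. The T cell and antigen presentation lists passed with each library left out, but their size depended on single libraries. The T cell median was -0.36 without hrLuc replicate 1 and -0.41 without hrLuc replicate 3, and the antigen presentation median was -0.14 without hrLuc replicate 1 and -0.40 without hrLuc replicate 2. The library scores of the groups overlapped for the T cell, antigen presentation and interferon lists (exact two-sided permutation p = 0.114, 0.143 and 0.314). The T cell score of hrLuc replicate 2 was -0.23, below those of S100a1 replicate 3 (-0.050) and S100a1 replicate 4 (-0.012). Without hrLuc replicate 1 CD3E was at -0.47, TAP1 at -0.22, TAPBP at -0.23, USP18 at -0.33, RTP4 at -0.25, STAT2 at -0.20 and TLR8 at -0.26. Without hrLuc replicate 2 CD3E was at -1.19, USP18 at -0.88, RTP4 at -0.77 and TLR8 at -0.75, and without S100a1 replicate 1 SLA-6 was at -0.24.

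The lists for endoplasmic reticulum stress, the cell cycle, immediate early genes and the S100 family were also lower, whereas 4 other stress lists did not pass. In the list for endoplasmic reticulum stress and the unfolded protein response 23 of 26 members were negative, with a median of -0.20 (adjusted p = 1.02e-04, camera, and adjusted p = 0.763 with an estimated correlation). The chaperones PDIA4 (-0.36 ± 0.11), DNAJB9 (-0.31 ± 0.10) and HSPA5 (-0.33 ± 0.11) and the secreted factor MANF (-0.33 ± 0.11) had the smallest p. Cell cycle genes had a median of -0.36, with 37 of 40 negative (adjusted p = 6.49e-05, camera, and adjusted p = 0.763 with an estimated correlation), among them the replication helicase genes MCM4 (-0.70) and MCM6 (-0.36) and the proliferation genes MKI67 (-0.70) and TPX2 (-0.74). Immediate early genes, which respond within minutes to stimuli, had a median of -0.18 (19 of 25 negative, adjusted p = 0.0255, camera, and adjusted p = 0.763 with an estimated correlation), and 4 members passed adjusted over the list alone. JUNB (-0.67 ± 0.12), FOSB (-1.60 ± 0.33) and FOS (-1.28 ± 0.36) were lower and MYC (0.55 ± 0.15) was higher. The S100 family, calcium-binding proteins related to the delivered gene, had a median of -0.31 (9 of 10 negative, adjusted p = 0.0295, camera, and adjusted p = 0.763 with an estimated correlation), with S100A16 at -0.31 and S100A10 at -0.20. S100A13 was at -0.34 in the transcript row kept but at 0.24 in its lowest and 0.23 in its middle row, and because it overlaps S100A1 the list can count the same reads for both. Heat shock and protein folding (median -0.07, adjusted p = 0.166, camera), the hypoxia response (median -0.02, 0.654), antioxidant defence (median -0.03, 0.771) and programmed cell death (median -0.11) did not pass. The cell cycle call was lost without hrLuc replicate 2 (adjusted p = 0.0554, camera), and its median was -0.23 without hrLuc replicate 1 and -0.20 without S100a1 replicate 1, whose score of -0.64 was the lowest. The immediate early call was lost without hrLuc replicate 2 (median -0.038, adjusted p = 0.427, camera) or S100a1 replicate 1 (-0.21, 0.142). It was also lost with a stricter filter (0.0514, camera), genes without overlap (0.0572) and the gene span trend removed (0.0568). The S100 call was lost without hrLuc replicate 1 (median -0.31, adjusted p = 0.0690, camera), hrLuc replicate 2 (-0.38, 0.0631) or S100a1 replicate 3 (-0.27, 0.0539), and its median was -0.20 without S100a1 replicate 4. The S100 call was also lost with the lowest (0.222, camera) or middle (0.166) transcript row and among genes without overlap (0.0780). The library scores of the groups overlapped for the cell cycle, immediate early and S100 lists. Without S100a1 replicate 1 MKI67 was at -0.43, TPX2 at -0.43 and S100A10 at -0.12, and without hrLuc replicate 1 MCM6 was at -0.18. S100A13 was at -0.21 without hrLuc replicate 3 or S100a1 replicate 4.

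The lists for oxidative phosphorylation, mitochondrial biogenesis and fatty acid oxidation were higher by small amounts, whereas the list for the TCA cycle and pyruvate oxidation did not pass (15 of 23 positive, median 0.04, adjusted p = 0.191, camera). Nuclear genes of oxidative phosphorylation had a median of 0.04, with 43 of 53 positive (adjusted p = 0.0118, camera, and adjusted p = 0.943 with an estimated correlation), led by the respiratory chain genes COX4I1 (0.24 ± 0.07) and NDUFS4 (0.22 ± 0.07), with COX6C at 0.19 (overlapping VPS13B) and COX7A1 at 0.16. Over all settings COX4I1 ran from 0.16 to 0.30 and NDUFS4 from 0.17 to 0.26. Regulators of mitochondrial biogenesis had a median of 0.11, with 15 of 20 positive (adjusted p = 0.0255, camera, and adjusted p = 0.763 with an estimated correlation). ESRRG, a nuclear receptor of oxidative metabolism, was at 0.66 ± 0.16 and passed adjusted over the list alone (0.0450, limma), although its lowest transcript row gave 0.30, with SIRT3 at 0.42, PPARGC1A at 0.31 and KLF9 at 0.34. Fatty acid oxidation genes had a median of 0.07, with 18 of 26 positive (adjusted p = 0.0420, camera, and adjusted p = 0.825 with an estimated correlation), with PDK4, which restrains pyruvate oxidation, at 0.80 ± 0.22 (overlapping ASB4), ACAA2 at 0.19, ETFB at 0.18 and SLC25A20 at 0.13. The oxidative phosphorylation call was lost without hrLuc replicate 1 (median 0.018, adjusted p = 0.311, camera), hrLuc replicate 2 (-0.0022, 0.524) or S100a1 replicate 2 (0.0058, 0.296), and its median was 0.13 without hrLuc replicate 3 and 0.088 without S100a1 replicate 4. The mitochondrial biogenesis call was lost without hrLuc replicate 2 (adjusted p = 0.0687, camera) and with the lowest transcript row (0.0581). The fatty acid call was lost without hrLuc replicate 1 (median 0.028, adjusted p = 0.482, camera), hrLuc replicate 2 (0.018, 0.449), S100a1 replicate 1 (0.023, 0.198) or S100a1 replicate 2 (0.109), and its median was 0.16 without hrLuc replicate 3 and 0.10 without S100a1 replicate 3. It was also lost without a filter (0.0676, camera) and among genes without overlap (0.0731). With quantile normalization, oxidative phosphorylation and fatty acid oxidation did not pass (0.398 each, camera). The library scores of the groups overlapped for these 2 lists. Without hrLuc replicate 2 COX7A1 was at 0.072, ETFB at 0.080, ACAA2 at 0.12 and KLF9 at 0.21, and without S100a1 replicate 2 COX6C was at 0.13 and PPARGC1A at 0.20. ACAA2 was at 0.30 without hrLuc replicate 3.

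**Figure D2:**
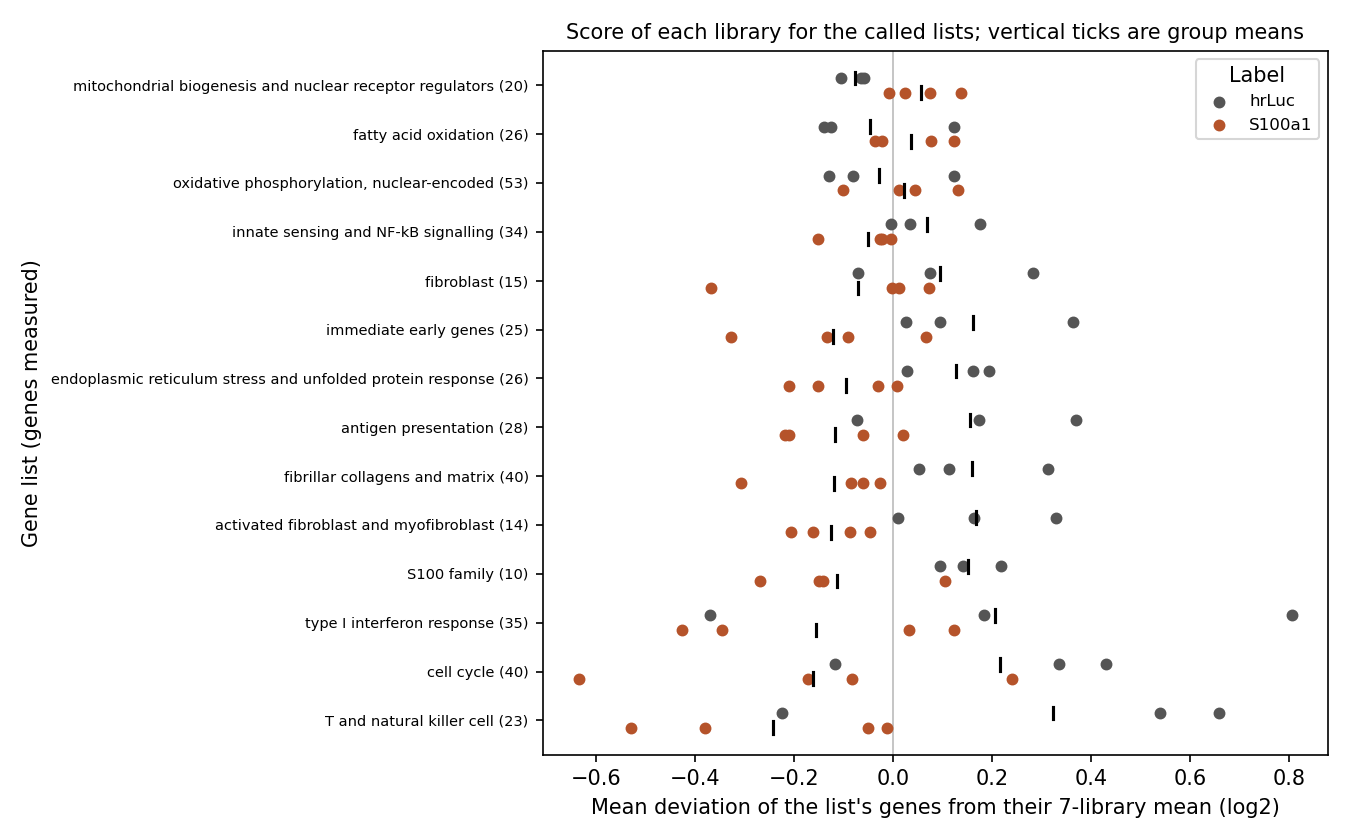
Score of each library for the 14 called lists, as the mean deviation of the list's genes from their mean over the 7 libraries on the log2 scale, where points are libraries, colours give the label and vertical ticks are group means. The hrLuc library at 0.81 on the interferon list stands apart from the other 6, and the groups do not overlap for fibrillar collagens and matrix.

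In all, 14 of 45 lists passed with the preset correlation, 11 of them lower and 3 higher, and 0 passed with an estimated correlation or with fry. Some lists share members, so the 14 calls are not independent. The preset of 0.01 treats the members of a list as nearly independent. Among the 14, the estimated correlation ran from 0.0077 for the S100 family to 0.76 for the interferon list. Without hrLuc replicate 1 the count of lists called was 9, without hrLuc replicate 2 it was 7 and without hrLuc replicate 3 it was 22. The library scores of the groups did not overlap in 5 of the 14. The 14 were called on these same libraries, so this share cannot be set against the 5.71% that chance gives for single comparisons. No list held a member past the threshold over all genes tested, and 7 lists held one adjusted over the list alone. The exact permutation test of the list scores gave its smallest possible p, 0.0286, for 5 lists, and adjusted over the 45 lists this was 0.257. These are not the same 5 as those above. They include B and plasma cells and programmed cell death, which were not called. They leave out endoplasmic reticulum stress and mitochondrial biogenesis (0.0571 each, exact permutation). Calcium handling genes did not pass (13 of 26 positive, median 0.02, adjusted p = 0.414, camera), nor did the sarcomere list (median 0.00, 0.269) or the natriuretic and fetal stress genes (median 0.03, 0.771). Vascular endothelium was at a median of -0.05 (0.891), and cardiomyocyte markers (0.06) and pericytes and smooth muscle (-0.23) did not pass either. Ribosomal protein genes were closest to the threshold among the rest (median 0.03, 0.0507). In the cardiac ion channel and atrial lists, which did not pass (0.109 and 0.891), KCNA5 passed adjusted over the list alone, as did KIT (-1.27) and FCER1A (1.57), named after their values were seen, in the neutrophil and mast cell list (0.269). The median, the mean and the direction of the test differed in sign for the lists of sarcomere and Z-disc, ubiquitin-proteasome and autophagy, hypoxia response, adipocyte, complement and coagulation, adrenergic, cyclic nucleotide and kinase signalling, angiogenesis and nitric oxide signalling, natriuretic and fetal stress genes, vascular endothelium and Schwann cell and neuron.

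The reference genes of remodelling and calcium handling that were fixed beforehand did not pass over all genes. RYR2, the calcium release channel, was at 0.42 ± 0.16 (adjusted p = 0.573, limma) and its groups did not overlap. PLN (overlapping CEP85L) was at 0.16, ATP2A2 (overlapping ANAPC7) at -0.15, MYH7 at 0.08, COL1A1 at -0.44, COL3A1 at -0.22 and POSTN at 0.08. Over all settings PLN ran from 0.060 to 0.22. NPPA was at 0.30 ± 0.32, with S100a1 replicate 4 far above the other 3 of its group, and NPPB at -0.32 ± 0.69, both smaller than their standard errors. Without S100a1 replicate 1 COL3A1 was at -0.056, and without hrLuc replicate 1 ATP2A2 was at -0.073. With a library left out MYH7, which was at 0.00 with quantile normalization, ran from 0.031 to 0.16, NPPA from -0.030 to 0.46, NPPB from -0.88 to 0.44 and POSTN from -0.068 to 0.18. The limma adjusted p of all 9 ran from 0.573 to 0.942.

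The authors' deposited table reported more genes, because it rests on other tests and on every transcript row. In it 559 transcript rows passed 0.05, 388 higher and 171 lower in S100a1, and these rows carried 134 gene symbols, 67 higher and 67 lower. GPRL15 had a log2 fold change of 1.43 and an adjusted p of 4.30e-13 in the authors' deposited table, and MMRN2 -0.90 and 2.64e-14. Of 1024 measured members of the lists fixed beforehand, 15 passed in the authors' deposited table, 6 higher and 9 lower. Those higher were RYR2 (0.42) and TRDN (0.48), parts of the calcium release unit, ESRRG (0.66), PDK4 (0.84), VEGFA (0.24) and AKAP6 (0.26). Those lower in the authors' deposited table were KCNA5 (-0.81), JUNB (-0.66), FOSB (-1.56), FOS (-1.34), SERPINF1 (-0.70), KIT (-1.28), CD5 (-1.15), ELN (-0.60) and MFAP4 (-0.50). Of these 15, RYR2, VEGFA, AKAP6 and ELN were not among the 100 genes that DESeq2 called with 1 transcript row per gene. S100A1 was at -0.38 with an adjusted p of 0.403 in the authors' deposited table. A refit with DESeq2 on the recovered reads of every row called 559 rows, all of them among the 559 deposited ones.

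The libraries did not part by label in rank correlation or on any single leading principal component. Rank correlations between libraries ran from 0.986 to 0.994, and the median was 0.991 within S100a1, 0.990 within hrLuc and 0.990 between the groups. The leading principal components of the 500 most variable genes held 23.1%, 20.5% and 18.4% of the variance, and on the leading one the hrLuc libraries lay from -20.9 to -3.47 and the S100a1 libraries from -3.92 to 15.6. No library looked like a duplicate deposit of another, since the chi-square per degree of freedom was at least 18.9 for every pair.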

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

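The tests of explanations for S100A1 and for gene span were chosen after the results had been seen, except that of the split with the most genes, as were the counts over other splits of the libraries. Among 91 results examined in the 4 S100a1 libraries, 3 had 1 library far from the other 3, and chance gives about 1 in 20 groups. NPPA was at 1095 normalized counts in S100a1 replicate 4, against 412 to 498 in the other 3, a gap of 0.875 of the range. GPC5 was at 186 in S100a1 replicate 1, against 133 to 141 in the other 3, a gap of 0.847 of the range. The score for innate sensing and NF-kB signalling was -0.15 in S100a1 replicate 1, against -0.026 to -0.0049 in the other 3, a gap of 0.858 of the range.

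Chance could not be excluded for any of the counts of calls. Of the 35 splits of the 7 libraries into 3 and 4, the labelled one included, 5 gave at least the 2 genes that limma called, the highest of the others being 3. For camera, 13 of 35 splits gave at least 14 lists, the highest of the others being 20. For DESeq2 on the recovered reads, 4 of 35 splits gave at least 100 genes. The highest of the other splits, which set hrLuc replicate 2 with S100a1 replicates 1 and 4, gave 207, although limma called 1 gene in it, and in simulation 17.7% of the calls of DESeq2 were false.

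The pig S100A1 gene was not higher in the libraries labelled S100a1 (log2 fold change -0.39). Reads shared with the overlapping S100A13 stay open as a source of the count, because the rows of S100A13 held from 2.97% to 76.1% of the S100A1 count and none of them separates the reads of the 2 genes. The trend with gene span was removed and the log2 fold change was -0.33, still below 0 by more than its standard error of 0.16. That human S100A1 reads were not counted on the pig transcripts may explain the absence of a rise, and the pig value of -0.39 cannot decide it without the reads on the human sequence. No biological explanation was tested, and exchanged labels stay open because this gene does not check them.

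Longer genes tended to be higher in the libraries labelled S100a1, with a rank correlation across genes of 0.184, and genes are not independent replicates. The trend differed among libraries within both groups, from -0.286 to 0.0826 in hrLuc and from -0.0812 to 0.204 in S100a1 (exact permutation p = 0.229), so a trend that varies between libraries whatever their group is a candidate explanation. It argues against the trend as the source of the list calls that 12 of the 14 lists were still called with it removed. For the other 2 the median moved toward 0, from -0.18 to -0.12 for immediate early genes (adjusted p = 0.0568, camera) and from -0.091 to -0.059 for innate sensing and NF-kB signalling (0.0701), so a part of the trend in these 2 calls and an effect of the vector on long genes stay open. The split with the most genes had 1873 genes at unadjusted p under 0.05 before removal and 1428 after it, still the most of the 35. What gene span predicts is therefore not the whole of that count. The 3 libraries of that split are the only ones with positive trends, so the trend may account for a part. The labelled split had 1294 genes at unadjusted p under 0.05 before removal and 1328 after it. At or above it, itself included, stood 4 of 35 splits before removal and 2 after it. With the trend removed limma called 3 genes in the labelled split, and 3 of 35 splits, itself included, gave at least as many. Removal takes out only what gene span predicts, so it cannot exclude a difference between libraries that goes with the trend.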

How the results depend on the processing

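The alternatives on the recovered reads, transcript rows, overlap and gene span were chosen after seeing the data. The 2 genes called (1 higher, 1 lower) became 3 (2 higher) with quantile normalization and with the gene span trend removed, 3 (2 higher) at a threshold of 0.10, 1 (0 lower) with median centring, 1 (0 lower) among genes without overlap, where MMRN2 is not tested, and 0 (0 higher, 0 lower; 1279 at an unadjusted p under 0.05) with limma-voom. DESeq2 gave 100 (55 higher, 45 lower). With a library left out the count ran from 0 to 3, with 0 to 1 higher and 0 to 3 lower. The 14 lists became 9 among genes without overlap, where fewer genes are tested (immediate early, S100, fibroblast, fatty acid and innate sensing lists did not pass), 0 with an estimated correlation and 0 with fry, and ran from 7 to 22 with a library left out. The labels number both groups from 1, but same-numbered libraries did not deviate together (correlations -0.0222, -0.0749 and 0.0823), and the replicate number as a block, which leaves out S100a1 replicate 4, called 0 genes (0 higher, 0 lower; 1011 at an unadjusted p under 0.05) and 16 lists. S100A1 was negative in every setting that tested it, from -0.50 to -0.25, and never passed. Named genes kept their sign except MYH7, which was at 0.00 with quantile normalization, NPPA (-0.030) and POSTN (-0.068) under the block, S100A13 with the lowest (0.24) or middle (0.23) transcript row, and, with a library left out, NPPA (-0.030 to 0.46), NPPB (-0.88 to 0.44) and POSTN (-0.068 to 0.18). Apart from counts and left-out libraries, 1330 values of genes and lists kept direction and side of the threshold, 50 no longer passed and 18 newly passed. Only the 2 called genes and the 14 called lists could lose a call. Most of the 1330 values belong to genes that did not pass in the main fit, so that count does not measure stability. The cause of the lost and new calls was not tested. The filter left 4992 of 20653 genes untested, and whether depth or lack of expression kept them below it was not examined.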

Other observations

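The genes of the next sentences, and the rule for when the test of gene overlap is uninformative, were chosen after the results had been seen. Beyond the called lists, several other genes separated the groups in DESeq2 on the recovered reads, a test whose calls were 17.7% false in simulation, so they are given as values. Higher in the libraries labelled S100a1 were the muscle genes PPP1R3A, a glycogen-targeting phosphatase subunit (log2 fold change 0.39, adjusted p = 0.00480, DESeq2), KLHL41 (0.53, 0.0282) and TXLNB (0.32, 0.0401), the ketone body enzyme gene BDH1 (0.33, 0.0453), the branched-chain keto acid dehydrogenase subunit gene BCKDHB (0.38, 0.0363) and the potassium channel gene KCNN2 (0.35, 0.0128). Lower were CD6, a T cell surface receptor encoded close to CD5 (-1.30, 0.00356), GRN, a lysosomal and secreted growth factor (-0.30, 0.0237), HYOU1, an endoplasmic reticulum chaperone outside the tested list (-0.38, 0.0401), and WIF1, a secreted WNT inhibitor (-1.44, 0.0453). None of these passed in limma, where the adjusted p ran from 0.415 to 0.541.

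GPRL15 and CDHR1 lie side by side on chromosome 14, which raised the hypothesis that genes with small p lie close together. Among the 100 genes with the smallest p, 97 were on a placed chromosome and formed 13 pairs within 1 Mb, where 10000 random sets had a median of 8 and an upper limit of 15 for their central range, so no excess was shown at this window. GPRL15 and MMRN2, the 2 genes called, start at 85404074 and 87891585 on chromosome 14. A window of 1 Mb cannot count that pair, so their nearness was not tested. Leaving out genes that overlap another gave 8 pairs among 78 genes (random median 5, upper limit 10), which cannot decide on shared reads because the full count had no excess either. The other 34 splits had a median of 11.5 pairs, between the median and the upper limit of the random sets, and 17 of 35 splits had at least 13 pairs, the highest of the others 81, so inherited differences between the pigs and the treatment could not be told apart here.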
